A study of Synechocystis sp. PCC 6803 with 12 samples.

How the data were processed

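RNA from 12 samples of the glucose-tolerant strain of Synechocystis and of a mutant described as lacking ndhD3, ndhD4, cmpA and sbtA was measured on 12 one-colour Agilent arrays, 2 per strain and sampling point. Per the labels, cells were grown in BG11 medium with 5% CO2, the mutant with selective antibiotics, pelleted and resuspended in medium of pH 7, kept at HC for 1 h and then bubbled with ambient air (0.035% CO2). Cells were collected by rapid filtration and RNA was labelled directly with Cy3, without cDNA synthesis. Per the file headers, the spot intensities were extracted with Feature Extraction 10.7.3.1, which subtracted background and detrended the processed signal and did not normalize between arrays. The deposited value table holds log2 values that have the same quantiles on every array, and the authors name limma for it without settings. These values follow the log2 mean signal (r of at least 0.996) more closely than the processed signal (r from 0.905 to 0.941), and they were used as an alternative only.

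Each array has 42303 spots, of which 1417 are controls, and the others carry 20363 probes for 8830 features. Spots of a probe were averaged on the log2 scale, and the value of a feature is the mean over its probes of the log2 processed signal minus the log2 of the array's 75th percentile. A feature was tested where at least 1 probe was well above background on both arrays of at least 1 group, which left 8231 features: 3279 genes, 1615 antisense, 1795 internal, 683 UTR, 540 non-coding, 276 other and 43 tRNA or rRNA features. No spot was saturated. Of the genes, 3259 have over 1 probe.

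Differences were estimated with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8; figures with matplotlib 3.10.9), with 1 mean per group over all 12 arrays, 6 residual degrees of freedom and moderated variances (2.31 prior degrees of freedom). The p-values were adjusted over all tested features by the Benjamini-Hochberg method, and a feature was called at an adjusted p under 0.05. Comparisons were LC 3 h and LC 24 h against HC in each strain, mutant against wild type at each sampling point, and the differences between the strains' responses. Groups of 2 arrays were not tested for outlying samples, and labels were not permuted, since splits of 2 against 2 arrays are too few to pass a threshold.

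The 28 gene lists, with gene symbols paired with locus tags from general knowledge, were fixed before the data were examined. They cover carbon uptake, genes beside the deletions, carboxysome and Rubisco, carbon regulators, flavodiiron proteins, nitrogen, glutamine synthetase inactivating factors, phycobilisome and its degradation, both photosystems, cytochrome b6f, NDH-1 core, ATP synthase, ribosomal proteins, chlorophyll, Calvin-Benson cycle, sugar catabolism, glycogen, photorespiration, chaperones, high light, iron, phosphate, pili, hydrogenase, terminal oxidases and sigma factors. Each was tested with camera, with its preset correlation of 0.01 and with an estimated correlation, and with fry. The estimated correlations ran from 0.131 to 0.994 across the lists, from 6 residual degrees of freedom. Such high estimates leave that test little power, so that a list that does not pass it is not shown to be unchanged. The preset of 0.01 lies below all of these estimates. Where the genes of a list vary together more than the preset allows, its p-values are too small. A list that passes with the preset alone is thus not shown to have changed as a set. The supplied annotation of 3347 genes shares 0 locus tags with the arrays, so that no genome position was used.

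The genes named were chosen by a fixed rule. It names the 4 deleted genes and, per comparison, the 6 largest rises and 6 largest falls among protein-coding features with an adjusted p under 0.05, a log2 difference of at least 1 and arrays that do not overlap between groups, or 4 and 4 for differences between responses. It adds up to 4 passing members of each list whose camera test passed, or the 2 largest where none passed, and the 2 largest rises and falls among non-coding and antisense features. The text names a selection of these, and members of lists beyond the rule were chosen after their values were seen.

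The alternatives planned were normexp background correction (offset 50), quantile normalization, median scaling, normexp with quantile normalization, the authors' value table, no background filter, the median over probes, an intensity trend, only the groups compared, blocks for slide, replicate number and strain with number, each array left out in turn, an adjusted p under 0.01, and the estimated correlation for lists. Others were added after seeing the data and are marked so, and the gene lists without wild type LC 3 h replicate 2 or mutant HC replicate 1 are among them, although leaving out each array was planned for the counts and named genes. On simulated data with 200 changed features among 8231, a log2 difference of 1 was recovered in 0.5% of cases for the wild type at LC 24 h and in 0% for the mutant against wild type at HC and for the difference of the LC 24 h responses. A difference of 2 was recovered in 87.5%, 81.5% and 52.5%, with 12, 10 and 8 false calls. In this simulation differences of 2-fold were thus mostly missed. Where more features change, smaller differences pass, and of 2122 calls in the wild type at LC 24 h 1308 were of 2-fold or more. A feature without a call is not shown to be unchanged.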

Results

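Transcript levels were measured in the cyanobacterium Synechocystis on 12 one-colour arrays, 2 for each of 6 groups. A glucose-tolerant wild type and a mutant of it were grown with air enriched to 5% CO2 (high CO2, HC) and then moved to ambient air with 0.035% CO2 (low CO2, LC). Cells were taken at HC and 3 h and 24 h after the move. No HC array is labelled as taken 3 h or 24 h later. In the comparisons of LC with HC, low CO2 thus cannot be told apart from time in culture. The mutant is described as lacking ndhD3 and ndhD4, which encode subunits of the NDH-1 complexes that take up CO2, cmpA, which encodes the binding protein of an ATP-driven bicarbonate transporter, and sbtA, which encodes a sodium-dependent bicarbonate transporter. Per the labels the mutant was grown with selective antibiotics, so that the strain comparisons cannot tell the deletions from the antibiotics. The design asks how each strain responded to low CO2, how the strains differed at each sampling point, and whether their responses differed. Each array reported 8830 features, of which 8231 were tested, 3279 of them protein-coding genes. The 75th percentile of the processed signal ran from 1894 to 4872 between arrays, and 74% to 93% of the probes were well above background. The authors describe the 2 arrays of a group as biological replicates. The p-values and standard errors rest on a single spread per feature, shared over the replicate pairs of all 6 groups. A wide pair thus enters comparisons that it is not part of, and is itself judged with a spread narrowed by the other pairs. Values are log2 signals relative to the 75th percentile of the array. Differences between groups are given on the log2 scale with the standard error of the limma fit (±, n = 2 arrays per group) and called at an adjusted p under 0.05.

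Replicate arrays correlated across features at r = 0.993 for the wild type at LC 24 h, 0.99 for the wild type at HC, 0.980 and 0.970 for the mutant at LC 24 h and LC 3 h, 0.945 for the wild type at LC 3 h and 0.916 for the mutant at HC. Features are not independent replicates, and these values describe the arrays only. Between the replicates of the mutant at HC 2024 features differed by 2-fold or more, and between those of the wild type at LC 3 h 1051 did, against 97 to 546 in the other 4 groups. Replicate 1 of the mutant at HC was also the dimmest array, with a 75th percentile of 1894 against 4609 on replicate 2, and its median tRNA and rRNA level lay 10.1 above its median gene level, against 8.33 on replicate 2. Each of the 3 slides held the 4 arrays of 1 sampling point. The strains were therefore compared within a slide, and a slide block leaves those comparisons as they are, whereas slide and sampling point cannot be told apart in the comparisons of LC with HC.

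**Figure D1:**
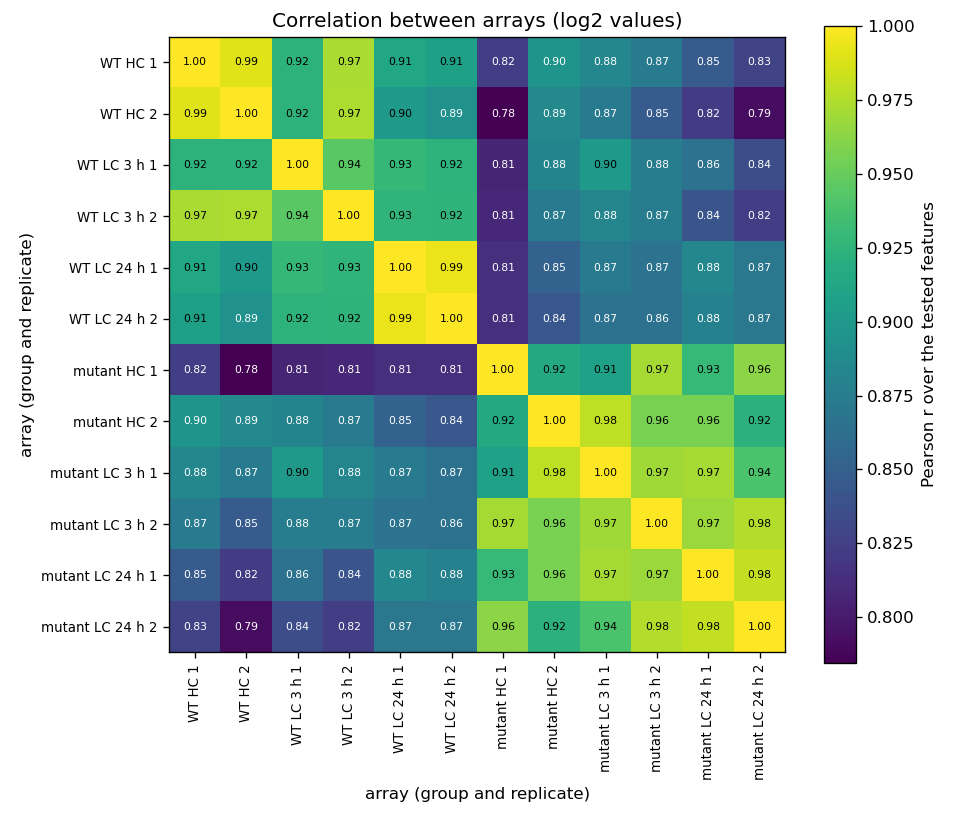
Pearson correlation across the 8231 tested features between each pair of the 12 arrays, with groups and replicates along both axes and the value of r printed in each cell. The replicates of the mutant at HC reach 0.916 and those of the wild type at LC 24 h 0.993.

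The deleted genes were examined first. ndhD4 was at 0.40 ± 0.19 (SD, n = 2) in the wild type at HC, 0.53 ± 0.22 at LC 3 h and 0.07 ± 0.28 at LC 24 h, and in the mutant at -2.98 ± 0.06, -2.71 ± 0.37 and -2.98 ± 0.40. The mutant lay below the wild type at all 3 sampling points, by -3.38 ± 0.27, -3.24 ± 0.27 and -3.06 ± 0.27 (adjusted p = 0.000134, 0.000165 and 0.000182). cmpA stood at -4.18 ± 0.46, 0.48 ± 4.83 and 3.01 ± 0.20 in the wild type and at -3.43 ± 0.22, -2.66 ± 0.46 and -3.09 ± 0.32 in the mutant. sbtA stood at -2.15 ± 0.02, 1.90 ± 3.70 and 2.82 ± 0.18 in the wild type and at -1.32 ± 0.03, 0.18 ± 0.31 and 0.35 ± 0.13 in the mutant. ndhD3 was at -3.67 ± 0.27, 0.79 ± 3.37 and 2.46 ± 0.05 in the wild type and at -0.38 ± 1.00, 1.60 ± 0.59 and 1.49 ± 0.19 in the mutant. Of these 3 genes, cmpA at LC 24 h was the one strain difference that passed (-6.10 ± 1.70, adjusted p = 0.0257), while ndhD3 at HC (3.29 ± 1.25, adjusted p = 0.0661) and sbtA at LC 24 h (-2.47 ± 1.30, adjusted p = 0.175) did not. These standard errors also hold the wide spread of the wild type LC 3 h pair, which is not among the arrays compared. Which part of each gene was removed is not given in the sources used here, and a probe outside the deleted part checks nothing about the deletion. Among the 4 probes of ndhD4, 2 were above background on 0 of the 6 mutant arrays and on 6 of the 6 wild type arrays, 1 was so on 5 mutant arrays, and 1 was bright on all arrays, at 2.19 to 4.17 in the mutant. All 4 probes of ndhD3 and all 4 of sbtA were above background on the 6 mutant arrays, and the 4 probes of cmpA were so on 6, 6, 3 and 4 mutant arrays. Of the sbtA probes, 2 stayed at -1.22 to -0.8 and -1.22 to -0.566 in the mutant, where the wild type reached 4.3 and 4.76, while the others reached 2.68 and 0.712 in the mutant against 4.41 and 4.59.

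**Figure D2:**
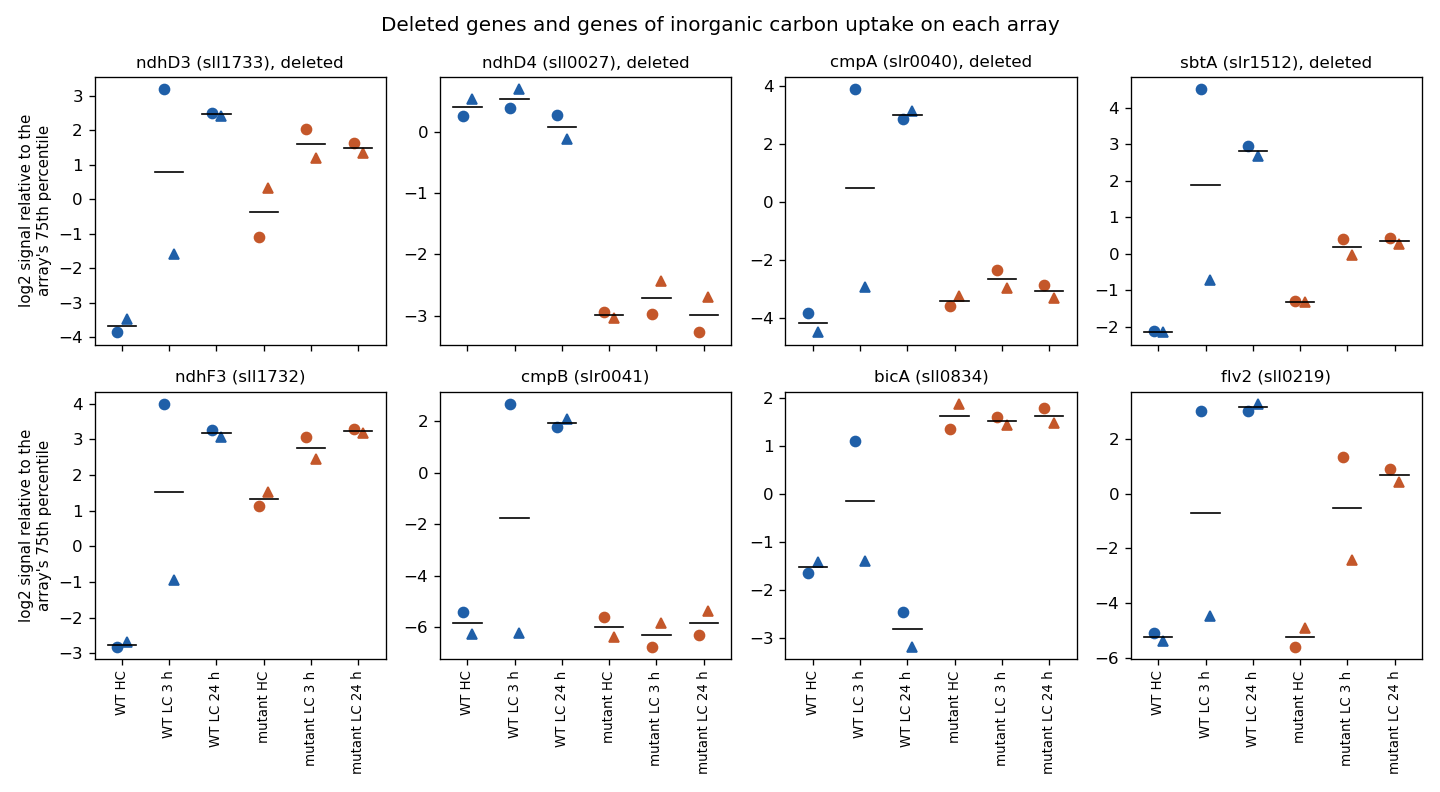
Log2 signal relative to the array's 75th percentile (vertical axes) of the 4 deleted genes and of ndhF3, cmpB, bicA and flv2 in the 6 groups (horizontal axes), with replicate 1 as circles, replicate 2 as triangles, wild type in blue, mutant in orange and the group mean as a line. In the wild type at LC 3 h cmpA lies at 3.89 on replicate 1 and at -2.94 on replicate 2.

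In the wild type at LC 3 h some chaperone genes were lower and some pilus genes higher, while most members of both lists did not pass. Neither list passed camera with an estimated correlation (adjusted p = 0.655 for each). In the list of 16 chaperones and proteases 4 fell, 0 rose and 12 did not pass: the chaperonin genes groES (-1.81 ± 0.20), groEL1 (-1.68 ± 0.24) and groEL2 (-1.54 ± 0.18), whose products fold proteins, and the protease gene htrA (-1.40 ± 0.28). In the list of 17 pili and motility genes 3 rose, namely the pilins pilA2 (2.44 ± 0.36) and pilA1 (1.70 ± 0.27) and the secretin gene pilQ (1.21 ± 0.17), 1 fell (slr2017, -1.79 ± 0.30) and 13 did not pass. Single members passed in 3 further lists. The chlorophyll-binding isiA rose by 1.11 ± 0.19 among the 13 iron genes, sigG rose by 1.25 ± 0.20 and sigH fell by 1.26 among the 9 sigma factor genes, and rpl4 fell by 0.76 among 49 ribosomal protein genes, of which 48 did not pass although 44 fell when adjusted over the list alone. Here and below, members of lists named where 5 or fewer passed include some that the fixed rule does not name, and these were chosen after their values were seen.

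At the same time point the genes of inorganic carbon uptake had large mean differences and a wide spread. limma called 0 of the 11 list members over all features, and 3 were higher and 1 lower adjusted over the list alone. Their median difference was 2.95. ndhF3, a subunit of the CO2 uptake complex of ndhD3, averaged 4.28 ± 1.23 (adjusted p = 0.136), and its arrays read 4.00 and -0.95 against -2.81 and -2.69 at HC. On the array labelled wild type LC 3 h replicate 2, cmpA, sbtA, cmpB and flv2 likewise lay closer to their HC levels than to their levels on replicate 1. Leaving out each array in turn was planned, but the list counts and gene values without this array and without mutant HC replicate 1 were chosen for reporting after seeing the data. Without this array 9 of the 11 rose and 1 fell, with ndhF3 at 6.75 ± 0.29 (adjusted p = 0.000113) and cupA at 5.25 ± 0.37, and ndhD3, cmpA and sbtA rose by 6.85 ± 0.57, 8.07 ± 0.39 and 6.66 ± 0.23. In that fit 3 of 5 flavodiiron genes rose (median of the list 7.79), as did both phycobilisome degradation genes (nblA1 3.90 ± 0.30, nblA2 3.79 ± 0.35) and 10 of 18 NDH-1 core genes, and 10 of 23 nitrogen genes fell and 1 rose. Of 22 chlorophyll synthesis genes 7 fell, of 25 photosystem II genes 4 fell, and of 12 high light genes 4 rose and 1 fell. When mutant HC replicate 1 was left out, 36 of 49 ribosomal protein and 7 photosystem II genes fell. With all arrays, 0 of these flavodiiron, nblA, NDH-1 core and nitrogen genes passed over all features and 2 nblA genes did adjusted over the list alone.

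For the wild type at LC 3 h limma called 188 of 8231 features (104 higher, 84 lower), of which 147 changed by 2-fold or more, with 38 protein-coding genes higher and 36 lower. Of the 28 lists, 13 passed camera with its preset correlation of 0.01: carbon uptake, genes beside the deletions (0 of 9 called, median 2.96), NDH-1 core (median 0.93), phycobilisome degradation and pili up, and ribosomal proteins (median -0.87), chaperones, photosystem II, ATP synthase, cytochrome b6f, chlorophyll synthesis, nitrogen and Calvin-Benson genes down. None of the 13 held with an estimated correlation (adjusted p = 0.655 with an estimated correlation for each). The cytochrome b6f and Calvin-Benson calls ended under quantile normalization (adjusted p = 0.0638 and 0.124), and without replicate 2 of the wild type at LC 3 h those of photosystem II, cytochrome b6f, ATP synthase, Calvin-Benson and pili did (0.137, 0.137, 0.114, 0.421 and 0.0502). In sugar catabolism, terminal oxidases and glycogen synthesis the median was negative (-0.08, -0.07 and -0.02) while camera's direction was up, with none of the 3 past the threshold. The files do not pair feature names with gene products; among features outside the lists, sll1696 rose by 2.72 ± 0.35, sll0384 fell by 3.83, and the antisense feature slr0421-as1 was at least 16.7-fold lower. Such a bound is given where the lower group was well above background on neither array, and takes each of its arrays at no less than the lowest probe well above background there. The count of 188 moved by over 1.5 times whichever array was left out: to 14 and 13 without replicates 1 and 2 of the wild type at HC, 37 and 979 without those of the wild type at LC 3 h, 96 without either wild type LC 24 h array, 430 without either mutant HC array, 94 without either mutant LC 3 h array and 89 without either mutant LC 24 h array.

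After 24 h at low CO2 the wild type had raised its carbon uptake genes, and lowered genes of photosynthesis, ATP synthesis, translation and nitrogen uptake. Of the 11 carbon uptake genes 8 rose, 1 fell and 2 did not pass. The transporter operon genes cmpB and cmpD were at least 94.6-fold and 65.6-fold higher, ndhF3 rose by 5.92 ± 1.23 and cupA by 5.18 ± 0.97, while cupB, which belongs to the constitutive CO2 uptake complex, fell by 1.41. All 9 genes beside the deletions are also in that list, and 8 of them rose, so that the 2 lists are not separate evidence. ndhD3 (6.12 ± 1.25), cmpA (7.19 ± 1.70) and sbtA (4.97 ± 1.30) rose, and ndhD4 did not pass (-0.32 ± 0.27). Among the 5 flavodiiron genes, flv2 and flv4, whose products accept electrons from photosystem II, were at least 222-fold and 138-fold higher. sll0218 of the same operon rose by 7.95 ± 2.29, and 2 genes did not pass. ndhR, which encodes a repressor of carbon uptake genes, was the 1 of 4 carbon regulators that rose (3.34 ± 0.67).

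Among the genes of light harvesting, 13 of 13 phycobilisome genes were lower, in a list that passed camera with the preset correlation and not with an estimated one. The linker gene cpcG2 fell by 6.62 (± 0.63) and the allophycocyanin genes apcA and apcB changed by -2.74 ± 0.31 and -2.66 ± 0.33. In photosystem I 8 of 12 fell, led by psaK1 (-1.76 ± 0.30) and psaL (-1.48 ± 0.28). In photosystem II 16 of 25 fell, led by psbO (-2.55 ± 0.24) and psbE (-2.00 ± 0.24), and the 3 that rose were psbA1, psbA2 and psbA3 (0.96 ± 0.30, 0.82 ± 0.18 and 0.82 ± 0.19). These encode the D1 protein and share much of their sequence, and their probes were not examined for cross-hybridisation. All 10 ATP synthase genes fell, with atpC at -3.24 ± 0.40 and atpA at -2.83 ± 0.39, and 8 of 12 cytochrome b6f and electron carrier genes fell, led by the ferredoxin gene petF (-2.70 ± 0.24). Among 49 ribosomal protein genes 44 fell and 5 did not pass, led by rpl24 (-2.99 ± 0.45) and rpl29 (-2.93 ± 0.45).

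In nitrogen metabolism 15 of 23 genes fell, including the nitrate transporter genes nrtD (-4.17 ± 0.43), nrtB (-4.04 ± 0.41) and nrtA (-3.84 ± 0.32) and the nitrate reductase gene narB (-3.61 ± 0.58). Both inhibitors of glutamine synthetase rose, gifA by 1.92 ± 0.37 and gifB by 1.10 ± 0.33. In the Calvin-Benson cycle 7 of 11 genes fell, led by rpiA (-3.42 ± 0.22), which encodes ribose 5-phosphate isomerase, and tktA, which encodes transketolase (-1.83 ± 0.31). Of 12 carboxysome and Rubisco genes 2 fell, the shell genes ccmK4 (-1.35 ± 0.24) and ccmK3 (-0.85 ± 0.17), and 10 did not pass. Photorespiration had 5 of 10 genes lower, led by glxK (-2.44 ± 0.36), and 1 higher (glcD1, 0.71 ± 0.15). Sugar catabolism had 4 of 14 lower, with gap1 at -2.03 ± 0.19, and glycogen synthesis 2 of 4, glgC (-1.71 ± 0.42) and glgA1 (-0.99 ± 0.24). Of 18 NDH-1 core genes 2 rose, ndhG (1.63 ± 0.50) and ndhK (1.45 ± 0.46), and of 22 chlorophyll and haem synthesis genes 6 fell, led by hemF (-2.38 ± 0.73). pilA2 (2.36 ± 0.36) and pilA1 (1.91 ± 0.27) led the 5 of 17 pilus genes that rose, while slr2015 to slr2018 made up the 4 that fell. In the remaining lists, 4 of 9 sigma factors rose and sigE fell, and 5 of 16 chaperones and proteases fell and hhoB rose. Of 12 high light and oxidative stress genes 3 fell (prxII, ocp and prx), isiA rose and futA1 fell among 13 iron genes, and pstS1 fell among 13 phosphate genes. None of 2 phycobilisome degradation, 5 hydrogenase and 8 terminal oxidase genes passed, in limma over all features or over the list alone. Without wild type LC 3 h replicate 2 these differences are unchanged but their standard errors are not, and then both phycobilisome degradation genes passed as higher (nblA1 1.97 ± 0.24, nblA2 1.58 ± 0.28), as did 10 of the 18 NDH-1 core genes, and 7 of the 12 high light genes fell (camera adjusted p = 0.0165). In the fit without mutant HC replicate 1, 10 chlorophyll synthesis genes fell and 8 pilus and 4 NDH-1 core genes rose.

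In all, 2122 features changed in the wild type at LC 24 h (976 higher, 1146 lower; 1308 by 2-fold or more), with 305 protein-coding genes higher and 566 lower. camera passed 15 lists: carbon uptake, genes beside the deletions, flavodiiron, glutamine synthetase inactivating factors, NDH-1 core and pili up, and nitrogen, phycobilisome, both photosystems, cytochrome b6f, ATP synthase, ribosomal proteins, chlorophyll synthesis and Calvin-Benson cycle down. None held with an estimated correlation (adjusted p = 0.547 to 0.646 with an estimated correlation). fry, which asks whether the genes of a list move one way on balance, passed 12. Between the strains it passed 14, 5 and 4 lists at HC, LC 3 h and LC 24 h. It passed 0 in the wild type at LC 3 h, in the mutant at LC 3 h and LC 24 h, and for both differences between responses. Counts adjusted over the list alone matched those over all features for carbon uptake (8 and 1), nitrogen (15 lower), phycobilisome (13 lower) and ATP synthase (10 lower), and were 47 for ribosomal proteins, 20 lower for photosystem II and 0 for NDH-1 core. Outside the lists, the non-coding feature NC-1134 rose by 6.20 ± 0.47 and slr0421-as1 was at least 14.5-fold lower. Leaving out 1 array moved the total by over 1.5 times for the arrays compared, to 1023 and 813 without replicates 1 and 2 of the wild type at HC and to 928 and 834 without those at LC 24 h. The flavodiiron, inactivating factor and pili calls ended under quantile normalization (adjusted p = 0.08, 0.0978 and 0.0949), and the first 2 of these also without mutant HC replicate 1 (0.082 and 0.0666).

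**Figure D3:**
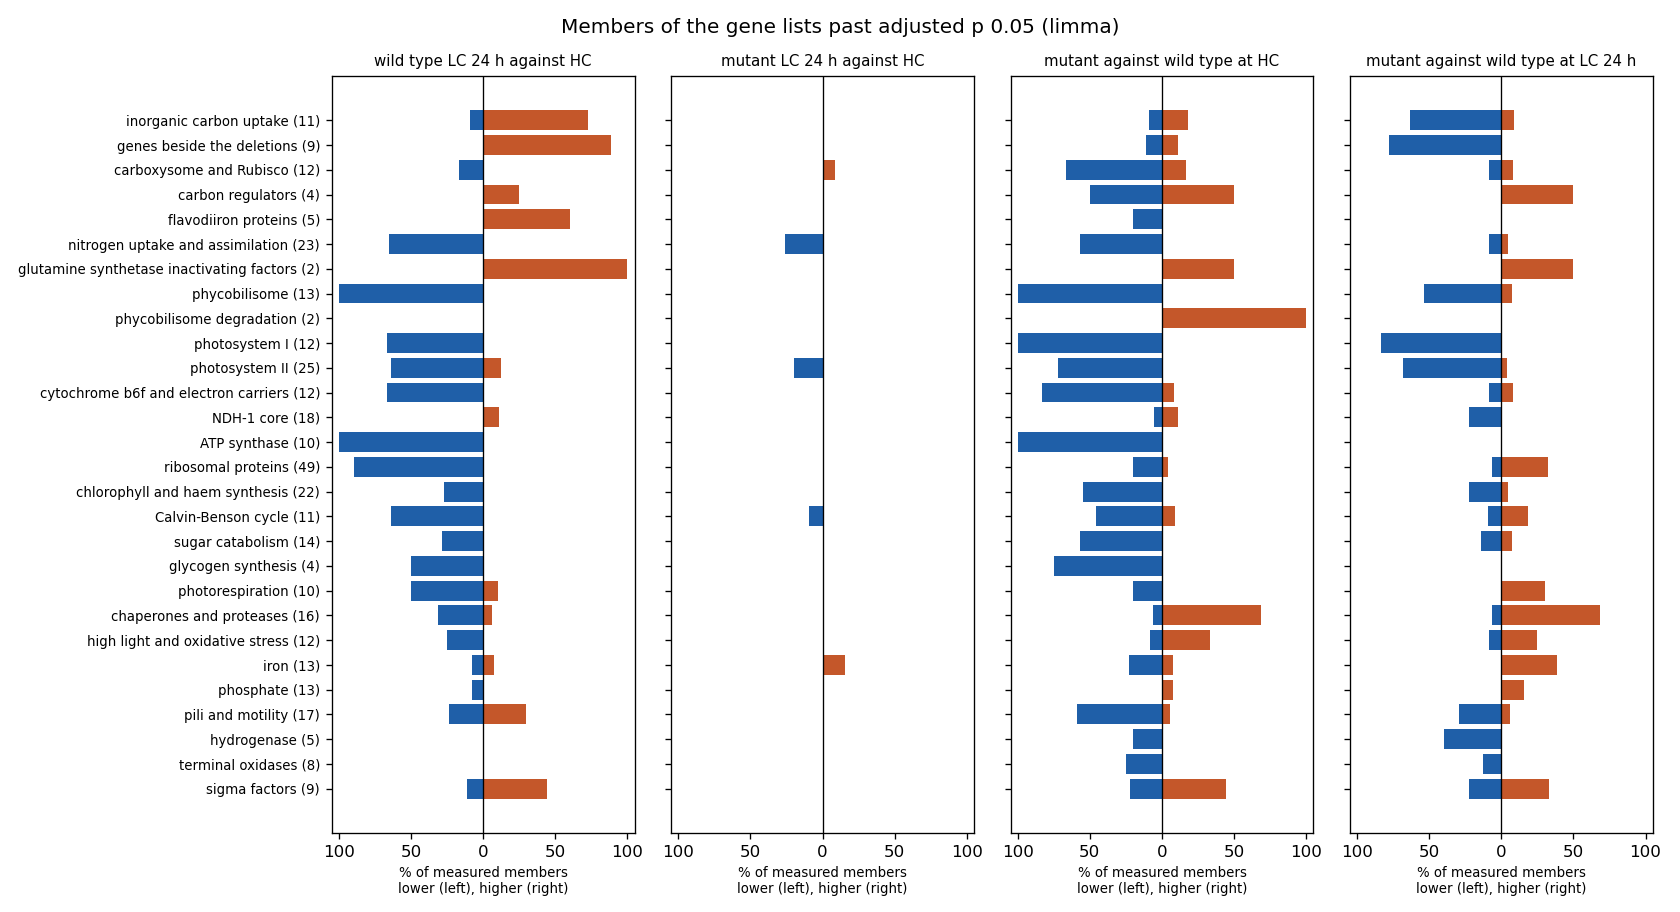
Percentage of the measured members of each gene list (list size in brackets) that were higher (orange, right of 0) or lower (blue, left of 0) at adjusted p under 0.05 in 4 comparisons. In the wild type at LC 24 h all 13 phycobilisome and all 10 ATP synthase genes were lower, and in the mutant at LC 24 h 0 of either list passed.

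In the mutant, 3 h at low CO2 changed 3 of 8231 features, all higher: sll1678 (2.09 ± 0.23), sll0225 (1.84 ± 0.20) and 1 feature that is not a protein-coding gene. No member of any list passed in limma over all features, where 561 features had an unadjusted p under 0.05. With array brightness as a covariate, chosen after seeing the data, 8 of 12 carboxysome and Rubisco genes, 1 pilus gene and 1 sigma factor gene rose. Adjusted over the list alone, 8 of 12 carboxysome and Rubisco genes rose, with rbcS, the small subunit of Rubisco, at 2.05 ± 0.43 (adjusted p over all features = 0.209) and its chaperone gene rbcX at 1.90 ± 0.42 (0.237), and 4 of 25 photosystem II genes fell. Carbon uptake genes had a median difference of 0.43 (0 of 11 passed), and ndhF3 stood at 1.43 ± 1.23. The nitrogen list had a median of -0.28, with nrtA at -1.35 ± 0.32 (adjusted p = 0.283). camera passed 9 lists, with carboxysome and Rubisco, photosystem I, NDH-1 core and pili up and nitrogen, photosystem II, cytochrome b6f, ribosomal proteins and chaperones down, and none with an estimated correlation (adjusted p = 0.785 with an estimated correlation for each). ATP synthase, chlorophyll synthesis and hydrogenase had a positive median (0.14, 0.07 and 0.02) and a negative camera direction, with no call. Without mutant HC replicate 2, 290 features were called, and without either array of the wild type at LC 3 h 5 were, while each other omission gave 0. Without wild type LC 3 h replicate 2 and mutant HC replicate 1 together, chosen after seeing the data, 33 were called. A fit over only the 4 arrays compared gave 0, as did the authors' value table. The ribosomal, chaperone and cytochrome b6f calls ended under quantile normalization (adjusted p = 0.139, 0.393 and 0.311), and the nitrogen call under normexp (0.0741). Those of photosystem I and pili ended without mutant HC replicate 1 (0.227 and 0.0889).

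In the mutant at LC 24 h some iron stress genes were higher and some nitrogen genes lower, while most members of both lists did not pass. Of 13 iron genes 2 rose, isiB (3.19 ± 0.37), which encodes flavodoxin, and isiA (2.17 ± 0.19), both known to be induced by iron limitation, and 11 did not pass. Of 23 nitrogen genes 6 fell, among them nrtB (-2.37 ± 0.41), the ammonium transporter gene amt1 (-2.29 ± 0.38), nrtD (-2.23 ± 0.43) and the nitrite reductase gene nirA (-1.90 ± 0.35). The photosystem II genes psbE (-1.29 ± 0.24), psbF (-1.10 ± 0.20), psbL (-1.06 ± 0.16), psbH (-0.87 ± 0.15) and psbJ (-0.84 ± 0.15) were the 5 of 25 that fell. rpiA fell by 1.16 (± 0.22) and rbcL, the large subunit of Rubisco, rose by 1.09 ± 0.20, each the 1 member of its list that passed. None of 11 carbon uptake, 5 flavodiiron, 13 phycobilisome, 10 ATP synthase and 49 ribosomal protein genes passed over all features. Without wild type LC 3 h replicate 2, 10 nitrogen genes fell and 3 of the 5 flavodiiron genes rose (flv2 5.90 ± 1.03, sll0218 5.73 ± 1.10, flv4 5.56 ± 0.80), as did 1 of the 11 carbon uptake genes, ndhF3 (1.91 ± 0.24). Adjusted over the list alone, 10 ATP synthase, 9 ribosomal protein, 3 phycobilisome, 10 nitrogen and 6 cytochrome b6f genes fell. flv2 stood at 5.90 ± 2.07 (adjusted p = 0.208), ndhF3 at 1.91 ± 1.23, and ndhD3, cmpA and sbtA at 1.86 ± 1.25, 0.34 ± 1.70 and 1.67 ± 1.30.

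The mutant at LC 24 h had 118 changed features (60 higher, 58 lower; 98 by 2-fold or more), with 17 protein-coding genes higher and 23 lower. Of these, 45 were also higher and 56 also lower in the wild type at LC 24 h, where independent lists would share 7.11 and 8.08. The comparisons share no arrays, but both set the LC 24 h slide against the HC slide and use the same variance per feature. A slide effect, time in culture or the shared variance could raise the overlap, so that it does not show a shared response to low CO2 by itself. camera passed 15 lists, none of them with an estimated correlation (adjusted p = 0.625 to 0.812 with an estimated correlation): carboxysome and Rubisco, flavodiiron, glutamine synthetase inactivating factors (gifA 1.48 ± 0.37, adjusted p = 0.0975), NDH-1 core, iron and pili up, and nitrogen, phycobilisome, photosystem II, cytochrome b6f, ATP synthase, ribosomal proteins, chlorophyll synthesis, Calvin-Benson cycle and high light genes down. The high light call ended under quantile normalization (adjusted p = 0.223). Sugar catabolism had a positive median (0.05) and a negative camera direction, without a call. Outside the lists, NC-425 rose by 2.98 ± 0.33 and the antisense feature sll0107-as1 was at least 5.28-fold lower. The spread of the mutant HC pair bears on each of these groups. Without mutant HC replicate 1 all 10 ATP synthase genes (median of the list -1.85), 27 of 49 ribosomal protein genes, 11 photosystem II, 9 nitrogen, 8 phycobilisome, 6 Calvin-Benson and 5 cytochrome b6f genes fell, and the total was 381. In that fit 0 carboxysome and Rubisco genes passed (rbcL 1.09 ± 0.25, adjusted p = 0.0543), and the camera calls of that list, flavodiiron, inactivating factor and high light genes ended (adjusted p = 0.08, 0.0677, 0.0677 and 0.144). Without mutant HC replicate 2 the total was 519, and it was 18 without either wild type HC array, 238 without either wild type LC 3 h array, 10 without either wild type LC 24 h array, 37 without either mutant LC 3 h array and 0 without either mutant LC 24 h array.

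**Figure D4:**
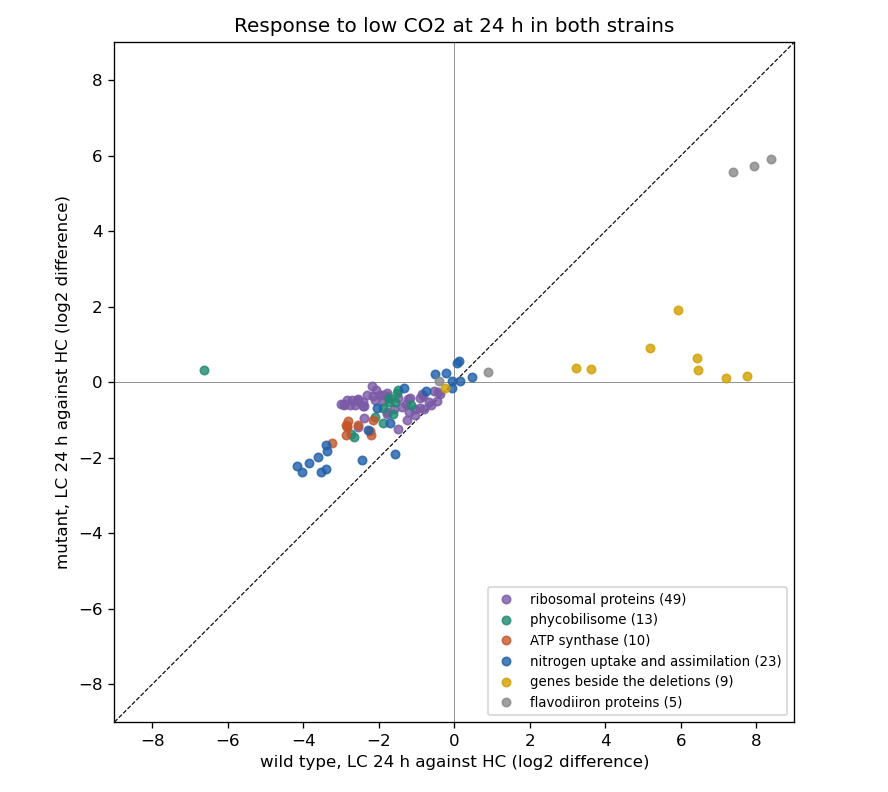
Log2 difference between LC 24 h and HC in the wild type (horizontal axis) and in the mutant (vertical axis) for the members of 6 gene lists, 1 point per gene, with the dashed line marking equal differences. cpcG2 lies at -6.62 in the wild type and close to 0 in the mutant, and ndhF3 at 5.92 in the wild type and 1.91 in the mutant.

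Already at high CO2 the mutant differed from the wild type in light harvesting, photosynthesis and stress genes. All 13 phycobilisome genes were lower, with cpcG2 at -4.99 ± 0.63 and the linker genes cpcC1 (-2.94 ± 0.35), cpcD (-2.90 ± 0.38) and cpcC2 (-2.88 ± 0.31), and both phycobilisome degradation genes were higher (nblA1 3.67 ± 0.75, nblA2 3.38 ± 0.71). All 12 photosystem I genes were lower, led by psaB (-3.07 ± 0.42) and psaK1 (-2.84 ± 0.30), as were 18 of 25 photosystem II genes, led by psbB (-1.94 ± 0.27). The same held for all 10 ATP synthase genes, led by atpG (-1.82 ± 0.44), and for 10 of 12 cytochrome b6f and electron carrier genes, led by petA (-1.75 ± 0.37). petJ was higher (0.55 ± 0.18). In the list of chaperones and proteases 11 of 16 were higher, among them htrA (3.77 ± 0.28), the small heat shock gene hspA (3.40 ± 0.52) and clpB1 (2.40 ± 0.34), and clpB2 was lower (-1.11 ± 0.29). Chlorophyll synthesis had 12 of 22 genes lower, led by chlL (-3.89 ± 1.27) and chlN (-3.15 ± 0.82), subunits of the light-independent protochlorophyllide reductase, and nitrogen uptake had 13 of 23 lower, led by amt1 (-1.89 ± 0.38).

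Among carbon genes at HC, 2 of 11 uptake genes were higher, ndhF3 (4.08 ± 1.23) and bicA (3.16 ± 0.67), which encodes the remaining known bicarbonate transporter, and ndhF4, next to ndhD4, was lower (-0.96 ± 0.15). The regulator genes cmpR (5.64 ± 1.06) and ndhR (5.12 ± 0.67) were higher and cyabrB2 (-1.10 ± 0.32) and cyabrB1 (-0.65 ± 0.20) lower, so that all 4 regulators passed. ndhD5, an NDH-1 gene that lies with slr2006 to slr2012, was higher by 5.28 ± 1.10 and ndhD6 by 2.43 ± 0.74, while ndhD1 was lower (-0.82 ± 0.25). Of 12 carboxysome and Rubisco genes 8 were lower, led by rbcS (-2.37 ± 0.43) and rbcX (-2.30 ± 0.42), and 2 higher (ccaA 0.66 ± 0.19, ccmO 0.65 ± 0.17). Sugar catabolism had 8 of 14 and glycogen synthesis 3 of 4 genes lower (glgC -1.43 ± 0.42, glgA2 -1.42 ± 0.33, glgA1 -0.94 ± 0.24). Calvin-Benson genes were lower in 5 of 11 cases, led by tktA (-1.33 ± 0.31), and cp12, which encodes an inhibitor of the cycle, was higher (1.76 ± 0.16). isiA (3.93 ± 0.19), the phosphate-binding protein gene sphX (2.50 ± 0.24) and the sigma factor genes sigB (3.26 ± 0.25), sigD (2.43 ± 0.45) and sigH (2.30 ± 0.16) were also higher. The sigma factor list had no single direction: with array brightness as a covariate, 5 of its 9 genes were higher and 4 lower. High light genes were higher in 4 of 12 cases (hliB 2.56 ± 0.63, hliC 1.34 ± 0.45, prxII 1.33 ± 0.19, ocp 1.08 ± 0.24) and lower in 1 (prx, -1.31 ± 0.23), and the iron genes feoB, bfrA and bfrB were lower. Pilus genes were lower in 10 of 17 cases, with pilB1 higher (0.89 ± 0.27), and ribosomal protein genes in 10 of 49, with 2 higher (rpl36 0.78 ± 0.16, rpl34 0.56 ± 0.19). gifB was the 1 of 2 inactivating factors that was higher (1.43 ± 0.33), flv1 the 1 of 5 flavodiiron genes that was lower (-0.73 ± 0.22), lpd and glcD2 the 2 of 10 photorespiration genes, hoxH the 1 of 5 hydrogenase genes and ctaE2 and ctaD1 the 2 of 8 terminal oxidase genes that were lower.

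At HC 3268 features differed between the strains (1681 higher and 1587 lower in the mutant; 2168 by 2-fold or more), with 459 protein-coding genes higher and 864 lower. Antisense features were higher in 639 and lower in 64 of 1615 cases, with a median difference of 0.69. camera passed 8 lists, with chaperones up and phycobilisome, both photosystems, ATP synthase, chlorophyll synthesis, nitrogen and cytochrome b6f down, none of them with an estimated correlation (adjusted p = 0.794 with an estimated correlation for each), and fry passed 14. Adjusted over the list alone, the counts were 13 lower for phycobilisome, 12 for photosystem I, 19 for photosystem II, 10 for ATP synthase, 17 for chlorophyll synthesis, 15 for nitrogen and 11 higher for chaperones. Carbon uptake, genes beside the deletions and photorespiration had a negative median (-0.00, -0.00 and -0.30) and a positive camera direction, without a call. Outside the lists, ssr2194 was higher by 6.09 ± 0.17, slr2076-as1 at least 42.4-fold higher, slr1584 lower (-3.45 ± 0.82) and slr0421-as1 at least 19.3-fold lower. The wide mutant HC pair enters all of these groups, and without its replicate 1 12 phycobilisome, 11 photosystem I, 17 photosystem II and 10 ATP synthase genes were lower and 11 chaperones higher. Other groups shrank in that fit: nitrogen from 13 to 5 lower, chlorophyll synthesis from 12 to 4, ribosomal proteins from 10 to 0, pili from 10 to 4, sugar catabolism from 8 to 3, carboxysome and Rubisco from 8 to 6, Calvin-Benson from 5 to 3, glycogen synthesis from 3 to 1, iron from 3 to 1, and carbon regulators, photorespiration and terminal oxidases from 2 to 0 each. The calls of flv1, hoxH, ndhD1, clpB2, pilB1, petJ, ccmO and ndhF3 ended as well. Carbon uptake went from 2 to 1 higher, and cytochrome b6f from 10 to 8 lower. The total fell to 1821 and 1448 without replicates 1 and 2 of the wild type at HC, and the cytochrome b6f call ended under quantile normalization (adjusted p = 0.106) and without wild type LC 3 h replicate 2 (0.0503), where 4 NDH-1 core genes were lower.

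The strain difference at HC was set against the response of the wild type to low CO2. Across the 8231 features, which are not independent replicates, the 2 sets of differences correlated at r = 0.308 (Spearman's rho 0.295) for the 3 h response and at r = 0.349 (rho 0.364) for the 24 h response. Both use the wild type HC arrays, and 100 simulations of unchanged groups against those arrays gave r = 0.498 and 0.496. The simulations gave all groups the same spread per feature, which by itself sets r near these values. The replicate differences had an SD of 0.34, 0.783 and 0.284 in the wild type at HC, LC 3 h and LC 24 h, and 0.975 in the mutant at HC. The simulated r is therefore no chance level for these arrays, and sets no bound for groups that changed. The covariances, to which the shared arrays add the same amount with or without changes, were 0.227 and 0.416, against 0.0758 and 0.0757 in the simulations, differences of 0.151 and 0.34. The same sign was found for 59.9% and 64.1% of features, against 66.7% and 66.6% simulated. The simulated covariances and shares rest on the same equal spread, and no conclusion is drawn from them. Most phycobilisome, photosystem, ATP synthase and nitrogen genes were lower in the mutant at HC and fell in the wild type at LC 24 h, where psbA1, psbA2 and psbA3 rose. For nitrogen genes the majority at HC was not kept without mutant HC replicate 1. In the wild type at LC 3 h 0 of these genes passed over all features, and photosystem I had a positive median (0.154). By contrast, groES fell by 1.87 in the wild type at LC 24 h and was higher in the mutant at all 3 sampling points.

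After 3 h at low CO2 the mutant again lay below the wild type in light harvesting and photosystem genes and above it in chaperones. Of 13 phycobilisome genes 11 were lower, led by cpcC1 (-3.02 ± 0.35) and cpcC2 (-2.95 ± 0.31), of 12 photosystem I genes 11, led by psaK1 (-2.73 ± 0.30), of 25 photosystem II genes 19, led by psbB (-1.88 ± 0.27). Of 12 cytochrome b6f and electron carrier genes 7 were lower, led by petA (-1.28 ± 0.37), with petJ higher (0.73 ± 0.18). Chaperones and proteases were higher in 11 of 16 cases, with htrA at 4.43 ± 0.28, hspA at 4.27 ± 0.52 and groES at 3.23 ± 0.20. Of 23 nitrogen genes 4 were lower, namely amt1 (-2.57 ± 0.38), the urea transporter gene urtA (-1.82 ± 0.27), gltB (-1.26 ± 0.21) and glnB (-0.74 ± 0.16). Pilus genes were lower in 5 of 17 cases, led by pilA2 (-2.17 ± 0.36). Of 11 carbon uptake genes ndhF4 alone passed (-0.56 ± 0.15), and the list had a median of -0.67. ndhF3 stood at 1.23 ± 1.23, with the wild type spread described above. Without the array labelled wild type LC 3 h replicate 2, 8 of the 11 were lower and 1 was higher, with cupA at -2.55 ± 0.37 and ndhF3 at -1.24 ± 0.29, and cmpA and sbtA differed by -6.55 ± 0.39 and -4.34 ± 0.23. Without replicate 1 in its place these 2 differed by 0.277 and 0.895 (adjusted p = 0.662 and 0.0295), so that sbtA was then called higher in the mutant. Other lists moved too. Without replicate 2 the cytochrome b6f list had 3 lower and 0 higher (petJ 0.73 ± 0.23, adjusted p = 0.0517), pili 3 lower, chlorophyll synthesis 1 lower and 3 higher, ATP synthase 0 and NDH-1 core 7 lower. When mutant HC replicate 1 was left out, 9 ATP synthase, 8 nitrogen and 8 pilus genes were lower.

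In this comparison 2300 features differed (1574 higher, 726 lower; 1437 by 2-fold or more), with 467 protein-coding genes higher and 316 lower. Antisense features were higher in 579 and lower in 40 cases (median 0.64). camera passed 9 lists, chaperones up and phycobilisome, both photosystems, cytochrome b6f, nitrogen, ATP synthase (1 of 10 called), chlorophyll synthesis (3 lower, hemE, chlH and hemB, and chlG higher) and pili down, and none held with an estimated correlation (adjusted p = 0.775 to 0.866 with an estimated correlation). Adjusted over the list alone, 13 phycobilisome, 12 photosystem I and 21 photosystem II genes were lower and 11 chaperones higher. Carboxysome and Rubisco genes had a negative median (-0.01) and a positive direction, and flavodiiron genes a positive median (0.17) and a negative direction, without a call. Outside the lists, ssr2194 was higher by 5.90 ± 0.17, NC-187 by 4.81 ± 0.46, and NC-1637 was lower (-2.97 ± 0.16). The total fell to 1318 and 1109 without replicates 1 and 2 of the mutant at LC 3 h. The ATP synthase, cytochrome b6f, chlorophyll and pili calls ended under quantile normalization (adjusted p = 0.192, 0.161, 0.127 and 0.0836). Without wild type LC 3 h replicate 2 the nitrogen and chlorophyll calls ended (0.113 and 0.422), and without mutant HC replicate 1 the pili call did (0.0685).

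At LC 24 h the genes beside the deletions had the largest median strain difference of the lists (-3.27), followed by carbon uptake (-3.21), which contains them. Of the 9 genes beside the deletions, 7 were lower in the mutant, 0 higher and 2 did not pass, with cmpB at least 101-fold lower, slr0042 at -7.42 ± 1.69, cmpD at -6.10 ± 1.09, cmpC at -5.85 ± 1.55 and cupA at -3.21 ± 0.97. cmpB to cmpD follow cmpA in its operon, and these values do not separate an effect of the deletion on neighbouring genes from regulation. ndhF3, whose level rose in the wild type, stood at 0.07 ± 1.23. Of the 11 carbon uptake genes 7 were lower and bicA was higher (4.46 ± 0.67). Of 25 photosystem II genes 17 were lower, led by psbT (-1.65 ± 0.17), with psb27 higher (0.51 ± 0.16). Of 12 photosystem I genes 10 were lower, led by psaA (-1.85 ± 0.27), and of 13 phycobilisome genes 7, led by cpcC1 (-1.67 ± 0.35), while cpcG2 was higher (1.96 ± 0.63). Ribosomal protein genes were higher in 16 of 49 cases, led by rpl3 (2.47 ± 0.18) and rpl4 (1.83 ± 0.15), and 3 were lower (rps10, rps1a and rpl9). Chaperones and proteases were higher in 11 of 16 cases, led by hspA (4.88 ± 0.52) and htrA (4.74 ± 0.28). Of 13 iron genes 5 were higher: isiA by 4.73 ± 0.19, isiB at least 5.32-fold, exbB at least 4.42-fold, and the iron transport genes futA1 (2.00 ± 0.36) and futC (1.09 ± 0.24). Chlorophyll synthesis had 5 of 22 genes lower, with acsF at -2.04 ± 0.52, and chlG higher (0.67 ± 0.17). In the fit without mutant HC replicate 1, 28 ribosomal protein genes were higher and 8 chlorophyll synthesis and 3 chaperone genes lower. Without wild type LC 3 h replicate 2, 9 chlorophyll synthesis and 9 NDH-1 core genes were lower, and 6 high light and both phycobilisome degradation genes higher.

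At LC 24 h 2807 features differed (1634 higher, 1173 lower; 1816 by 2-fold or more), with 474 protein-coding genes higher and 535 lower, and antisense features higher in 577 and lower in 88 cases (median 0.56). camera passed 8 lists, ribosomal proteins, chaperones and iron up and genes beside the deletions, phycobilisome, both photosystems and chlorophyll synthesis down, and none held with an estimated correlation (adjusted p = 0.834 with an estimated correlation for each). Adjusted over the list alone, 23 ribosomal protein genes were higher, and 17 photosystem II, 11 photosystem I and 8 of the genes beside the deletions were lower. Calvin-Benson, sigma factor and inactivating factor genes had a negative median (-0.45, -0.22 and -0.06) and a positive camera direction, without a call. Outside the lists, slr0967 was higher by 5.23 ± 0.15, slr2076-as1 at least 40.5-fold higher and NC-248 at least 7.42-fold lower. The total fell to 1466 and 1391 without replicates 1 and 2 of the wild type at LC 24 h and to 1582 and 1433 without those of the mutant. The phycobilisome call ended under quantile normalization and normexp (adjusted p = 0.087 and 0.159), and the genes beside the deletions and photosystem II did so under normexp (0.0531 and 0.0798), as did chlorophyll synthesis (0.0798).

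Across the 3 sampling points, 1025 features were higher and 423 lower in the mutant every time, among them 267 and 184 protein-coding genes. The comparisons at HC and LC 3 h shared 1276 higher and 587 lower features, where independent lists would share 321 and 140, those at HC and LC 24 h shared 1140 and 745 (334 and 226), and those at LC 3 h and LC 24 h shared 1194 and 486 (312 and 103). These comparisons use separate arrays but the same variance per feature, which can raise the overlap. The sigma factor genes sigB (3.26 ± 0.25, 2.33 ± 0.25 and 2.37 ± 0.25) and sigH (2.30 ± 0.16, 3.30 ± 0.16 and 2.52 ± 0.16) and ocp, which encodes the orange carotenoid protein of photoprotection (1.08 ± 0.24, 1.24 ± 0.24 and 1.71 ± 0.24), were higher at HC, LC 3 h and LC 24 h, and were picked out after their values were seen. Other sigma factor genes were lower: with the brightness covariate 4 of 9 were higher and 4 lower at LC 3 h, and 3 higher and 5 lower at LC 24 h.

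**Figure D5:**
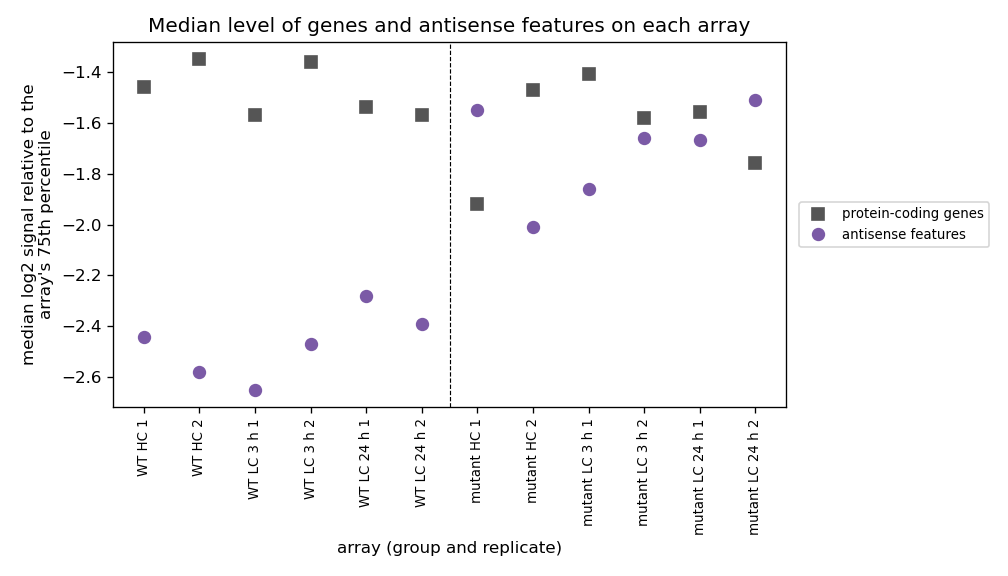
Median log2 signal relative to the array's 75th percentile (vertical axis) of protein-coding genes (squares) and antisense features (circles) on each of the 12 arrays (horizontal axis), wild type left of the dashed line and mutant right of it. The antisense medians reach at most -2.28 on the 6 wild type arrays and at least -2.01 on the 6 mutant arrays.

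The test of the difference itself asked whether the strains responded differently. For the 3 h responses limma called 0 of 8231 features, with 444 at an unadjusted p under 0.05. ndhF3 stood at -2.85 ± 1.75 and nblA1 at -2.74 ± 1.06 (adjusted p = 0.836), meaning a smaller difference in the mutant, and rbcS at 1.85 ± 0.61 (adjusted p = 0.836). Adjusted over the list alone, 8 of 12 carboxysome and Rubisco genes were higher and both phycobilisome degradation genes lower. camera passed 7 lists, carboxysome and Rubisco, ATP synthase and ribosomal proteins up and carbon uptake, genes beside the deletions, phycobilisome degradation and high light genes down, none with an estimated correlation (adjusted p = 0.836 to 0.994 with an estimated correlation). For nitrogen, photosystem II, NDH-1 core, flavodiiron and pilus genes the median was positive and camera's direction negative, without a call. Without the array labelled wild type LC 3 h replicate 2, 319 features were called, with 9 of 11 carbon uptake genes lower and 1 higher, all 8 genes beside the deletions that passed lower, ndhF3 at -5.32 ± 0.38 and nblA1 at -4.19 ± 0.38. Without replicate 1 in place of replicate 2, cmpB went from -4.37 to 0.0815 and sbtA from -2.55 to 0.0686, so that these differences rest on replicate 1. The authors' value table gave 8 calls and quantile normalization 1. The carbon uptake call ended under normexp (adjusted p = 0.0965) and the high light call under quantile normalization (0.517). The carbon uptake, high light and ATP synthase calls ended without mutant HC replicate 1 (0.0651, 0.0651 and 0.166), and without wild type LC 3 h replicate 2 the ATP synthase call did (0.243).

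For the 24 h responses 49 features differed (32 higher and 17 lower in the mutant's response), 13 protein-coding genes higher and 3 lower. cpcG2 differed by 6.95 ± 0.89, having fallen by 6.62 in the wild type while it stood at 0.33 ± 0.63 in the mutant, where it was already low at HC. The ribosomal protein genes rpl3 (2.07 ± 0.25), rpl23 (1.79 ± 0.30) and rpl4 (1.65 ± 0.22) were the 3 of 49 that passed, with 27 adjusted over the list alone and 23 over all features with the brightness covariate. rpiA (2.27 ± 0.31) and groES (1.85 ± 0.28) were the 1 gene each that passed among 11 Calvin-Benson and 16 chaperone genes. None of the 11 carbon uptake genes passed over all features, and 4 were lower adjusted over the list alone: cupA stood at -4.27 ± 1.37 and ndhF3 at -4.01 ± 1.75, and the deleted genes cmpA, ndhD3 and sbtA at -6.85 ± 2.41, -4.26 ± 1.77 and -3.30 ± 1.83 (adjusted p = 0.237, 0.296 and 0.435). Without wild type LC 3 h replicate 2 these differences are unchanged with smaller standard errors, and 8 of the 11 carbon uptake genes were lower and 1 higher, with cupA at -4.27 ± 0.43 and ndhF3 at -4.01 ± 0.34 (adjusted p = 0.00745 and 0.00433). Of the 9 genes beside the deletions 8 were lower in that fit, and cmpA, ndhD3 and sbtA passed (adjusted p = 0.00278, 0.0261 and 0.00433). camera passed 12 lists, carbon uptake and genes beside the deletions down and carboxysome and Rubisco, nitrogen, phycobilisome, both photosystems, cytochrome b6f, ATP synthase, ribosomal proteins, Calvin-Benson cycle and iron up, none with an estimated correlation (adjusted p = 0.616 to 0.671 with an estimated correlation). Pili and terminal oxidases had a positive median (0.24 and 0.11) and a negative direction, without a call. Without mutant HC replicate 1 cpcG2 alone passed (5.81 ± 0.47, adjusted p = 0.0263), rpl3 and rpiA had an adjusted p of 0.0676, and the Calvin-Benson camera call ended (0.0549). Without mutant HC replicate 2 the total was 859, without either wild type LC 3 h array 183, and 0 without any other single array.

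The covariate for array brightness, chosen after seeing the data, also moved list counts in the other comparisons. In the wild type at LC 3 h 46 of 49 ribosomal protein, 9 of 10 ATP synthase, 8 of 12 cytochrome b6f and 8 of 25 photosystem II genes then fell, and at LC 24 h 12 of 18 NDH-1 core and 9 of 17 pilus genes rose. For the mutant at LC 24 h all 10 ATP synthase, 19 ribosomal protein, 12 photosystem II, 6 Calvin-Benson and 4 phycobilisome genes fell, and 8 pilus and 7 carboxysome and Rubisco genes rose. Between the strains, 26 ribosomal protein, 16 chlorophyll synthesis and 6 NDH-1 core genes were lower in the mutant at HC, and 10 ATP synthase, 10 nitrogen and 9 pilus genes at LC 3 h. At LC 24 h 13 chlorophyll synthesis, 12 NDH-1 core, 12 pilus, 8 carboxysome and Rubisco and 7 terminal oxidase genes were lower, and 21 ribosomal protein genes higher. Of the 4 carbon regulators there, 2 were higher without the covariate, and 0 were higher and 2 lower with it. The median of the list stayed positive with it (0.383), and these counts do not show that the same genes turned. In the difference of the 24 h responses 1 of 11 carbon uptake genes was lower, and for the 3 h responses 0 list members passed. The carbon uptake call of camera in the wild type at LC 24 h ended (adjusted p = 0.0707), as did those of the genes beside the deletions and phycobilisome between the strains at LC 24 h (0.0805 and 0.0564) and of nitrogen in the wild type at LC 3 h (0.108).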

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

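The test of the difference between the strains' responses flagged 15 features by the fixed rule and their total number, all for the 24 h responses. The total was 49 features. cpcG2 differed by 6.95, rpiA by 2.27, rpl3 by 2.07, rpl23 by 1.79 and rpl4 by 1.65. Outside the lists, the response of the mutant was higher for sll1472 (4.58) and lower for slr1456 (-2.12) and the non-coding feature NC-1136 (-3.82). The other flagged genes differed by 2.52, 2.46, -1.85 and -1.31, and the other non-coding and antisense features by 2.68 (NC-520, at background in the wild type at LC 24 h) and -2.48. The fitted value for the antisense feature slr0421-as1 was 5.09, but it was above background in the wild type at HC alone, so that the value reflects its fall there and is no measured response of the mutant. Without mutant HC replicate 1 cpcG2 alone passed.

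For 3 patterns technical explanations were tested. The predictions of 5 of the 6 tests were written after the result was seen, and that of the test of dim probes before it was run.

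The array labelled wild type LC 3 h replicate 2 lacks the rise of the inorganic carbon genes. An HC sample under a wrong label would lie 2-fold away from an HC array as often against the direction of the 24 h change as with it. Among features that had not moved that way in the mutant at 3 h, 50 lay with and 4 against it when picked with HC replicate 1 and compared with replicate 2, and 29 and 16 in the converse split. The second split is too even to argue against a wrong label, and HC and LC 3 h lie on separate slides, so that this explanation stays open. A uniform mixture of LC 3 h and HC RNA would reach an equal share of each rise. The share ran from 0.915% at the lower quartile to 17.3% at the 90th percentile of 60 genes. Noise can spread shares this small as widely, so that this range does not decide. Among genes picked by name, the share ran from -0.0647% (cmpB) to 2.83% (ndhD3) for carbon uptake and flavodiiron genes, with cmpA at 0.509%. It was 60% for pilA1 and 50.2% for pilA2. For these few genes the shares argue against a uniform mixture. A slower or weaker exposure of that culture to low CO2 was not tested, and the data give no means to test it.

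The mutant HC arrays differ along an axis that other replicate pairs share. In 5 of 5 other pairs the brighter array lies on the side of the brighter mutant HC array, which fits array brightness as an explanation, although the correlation was weak in the wild type at LC 3 h (-0.0626) and the wild type at LC 24 h (-0.22). It was 0.51 in the wild type at HC, and strong in the mutant at LC 3 h (-0.863) and LC 24 h (-0.845). The GC content of the probes correlated with the difference at r = 0.158, which argues against it. Brightness may stand for the amount or quality of the RNA, which the files do not give.

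Antisense features were higher in the mutant at every sampling point. Array brightness does not account for it, since the lowest antisense median of a mutant array lay 0.272 above the highest of a wild type array while brightness overlapped. Genes matched in level to the antisense features had a median difference of -0.243 at HC, against 0.688 for the antisense features, which argues against a background or DNA signal common to dim probes. The medians at HC, LC 3 h and LC 24 h depended on background correction, at 0.458, 0.225 and 0.157 under normexp and 0.254, 0.159 and 0.172 in the authors' value table. A difference between the strains remains an open hypothesis, and contaminating DNA that reaches some probes more than others was not tested.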

How the results depend on the processing

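Alternatives chosen after seeing the data are those without both wild type LC 3 h arrays, without wild type LC 3 h replicate 2 and mutant HC replicate 1 together, with the crossed replicate block, scaled on genes alone and with the brightness covariate, and for the gene lists and the correlation at HC also those without wild type LC 3 h replicate 2 or mutant HC replicate 1; the others, with each array left out in turn, were planned. Of 373 named results 358 kept their sign under every alternative and 15 changed it, 13 of them without passing in either fit. In the mutant against wild type at LC 3 h, sbtA ran from 0.895 without wild type LC 3 h replicate 1 (adjusted p = 0.0295) to -4.34 without replicate 2. ndhD3 turned from 0.802 to -1.58 without replicate 2 (adjusted p = 0.0859), and passed at -1.58 without the 2 arrays (0.0134). cmpA turned from -3.14 to 0.277 without replicate 1, and so did sbtA in the difference of the LC 3 h responses, from -2.55 to 0.0686. ndhF3, which the fixed rule does not name for mutant against wild type at LC 3 h, went from 1.23 to -1.24 without replicate 2. No list that passed camera changed direction, and the 96 calls of the gene lists became 0 with an estimated correlation and 91 to 114 without wild type LC 3 h replicate 2 or mutant HC replicate 1. Where counts moved in a comparison that holds the array left out, or under other settings, the cause was not tested. An array left out or a stricter threshold leaves less to test with. In comparisons that an array is not part of, leaving it out changes no difference and takes its pair out of the shared spread. The number of called features was then the same whichever array of the pair was left out. It rose for the 2 widest pairs only, mutant HC and wild type LC 3 h (SD of the replicate difference 0.975 and 0.783). A group left with 1 array is assumed to vary like the others.

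Counts of changed features moved in every comparison. For wild type LC 3 h against HC (188) they were 0 with only the groups compared, 291 in the authors' value table, 1866 without the 2 arrays, 1085 with the brightness covariate, 39 at an adjusted p under 0.01 and 13 to 979 with an array left out. For wild type LC 24 h against HC (2122) they were 4265 with only the groups compared, 3540 without the 2 arrays, 3396 with brightness, 954 at the stricter threshold and 813 to 2922 with an array left out. For mutant LC 3 h against HC (3) they were 0 with only the groups compared, 6 with quantile normalization, 6 with median scaling, 0 with normexp and quantile, 0 in the authors' table, 1 with an intensity trend, 5 without both wild type LC 3 h arrays, 33 without the 2 arrays, 6 scaled on genes alone, 91 with brightness, 0 at the stricter threshold and 0 to 290 with an array left out. For mutant LC 24 h against HC (118) they were 0 with only the groups compared, 248 with normexp, 293 with quantile normalization, 188 with median scaling, 249 with normexp and quantile, 222 in the authors' table, 63 with no background filter, 238 without both wild type LC 3 h arrays, 825 without the 2 arrays, 227 scaled on genes alone, 1099 with brightness, 0 at the stricter threshold and 0 to 519 with an array left out.

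For mutant against wild type at HC (3268) the count was 673 with only the groups compared, 1598 at the stricter threshold and 1448 to 4412 with an array left out. For mutant against wild type at LC 3 h (2300) it was 1052 with only the groups compared, 4092 with brightness, 1179 at the stricter threshold and 1109 to 3115 with an array left out. For mutant against wild type at LC 24 h (2807) it was 4227 with only the groups compared, 4355 without the 2 arrays, 4640 with brightness, 1437 at the stricter threshold and 1391 to 3643 with an array left out. For the difference of the LC 3 h responses (0) it was 1 with quantile normalization, 8 in the authors' table, 451 without the 2 arrays, 3 with brightness and 0 to 319 with an array left out. For the difference of the LC 24 h responses (49) it was 85 with normexp, 78 with median scaling, 96 with normexp and quantile, 133 in the authors' table, 183 without both wild type LC 3 h arrays, 243 without the 2 arrays, 113 scaled on genes alone, 631 with brightness, 0 at the stricter threshold and 0 to 859 with an array left out.

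The replicate numbers pair nothing that the labels state, and of 15 pairs of groups 6 had a correlation over 0.1, while all 15 ran from -0.863 to 0.829. With a replicate block by number the counts were 97 for wild type LC 3 h against HC, 0 for mutant LC 3 h against HC, 53 for mutant LC 24 h against HC and 0 for the difference of the LC 24 h responses, and with a replicate block by strain and number 76, 0, 8 and 0. The replicate difference of the mutant at HC correlated at -0.863 and -0.845 with those of the mutant at LC 3 h and LC 24 h, which correlated at 0.829 with each other. Crossed numbers of the 2 mutant HC arrays would give these signs, but so would array brightness. The wild type HC pair also correlated with the mutant pairs at HC, LC 3 h and LC 24 h (0.51, -0.468 and -0.495), which crossed mutant numbers do not account for. A crossing is thus not shown. The crossed replicate block, in which the 2 numbers of the mutant HC arrays are exchanged, was chosen after these correlations were seen, and its counts are no evidence for a crossing. With it the counts were 761 for wild type LC 3 h against HC, 3541 for wild type LC 24 h against HC, 85 for mutant LC 3 h against HC, 782 for mutant LC 24 h against HC, 6 for the difference of the LC 3 h responses and 588 for the difference of the LC 24 h responses.

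The correlation of the strain difference at HC with the 3 h response was 0.321 with normexp, 0.358 for genes alone and 0.28, 0.295 and 0.342 without mutant HC replicate 1, mutant HC replicate 2 and wild type LC 3 h replicate 2. With the 24 h response it was 0.266, 0.371 and 0.349 without these arrays. The share of higher features among those called depended on the scale. For mutant against wild type at LC 3 h it was 68.4% and became 48.7% with normexp, 57.1% with quantile normalization, 54.9% with both and 55.1% in the authors' table, and at LC 24 h 58.2% became 41.1% with normexp. For mutant LC 24 h against HC 50.8% became 38.7% with normexp and 65.3% in the authors' table, for mutant LC 3 h 100% became 75% with normexp and 66.7% with median scaling, and for the difference of the LC 24 h responses 65.3% became 44.7% with normexp. The median over all features also moved by over 0.1 in places. With normexp it went from 0.017 to -0.0986 for mutant LC 3 h against HC, from 0.0442 to -0.0628 for mutant LC 24 h against HC, from 0.073 to -0.0568 and from -0.0033 to -0.139 for the strains at LC 3 h and LC 24 h, and from 0.112 to -0.0827 and from 0.0212 to -0.168 for the differences of the LC 3 h and LC 24 h responses. With median scaling it went to -0.0855 for mutant LC 3 h against HC, from -0.00903 to 0.0926 for the strains at HC (0.12 scaled on genes alone), and to -0.0266 for the difference of the LC 3 h responses (-0.0138 with quantile normalization, -0.0248 with both, -0.0184 in the authors' table). Between 74% and 93% of probes were well above background, which limits what can be said of dim features.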

Other observations

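Antisense features and the genes they lie opposite were compared in 1593 pairs. Their strain differences correlated at r = 0.0804 at HC, 0.0821 at LC 3 h and 0.055 at LC 24 h. The gene was lower in 20.3% of pairs whose antisense feature was higher, against 28.7% of the other pairs at HC, and in 6.57% against 9.36% at LC 3 h and 14.1% against 15.7% at LC 24 h.

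In the strain comparisons the phosphate-binding protein gene sphX was higher at LC 3 h (2.68 ± 0.24) and LC 24 h (2.45 ± 0.24) as well as at HC, and the chaperone gene clpB1 at LC 24 h (2.63 ± 0.34). For 1 to 42 of 3259 genes per comparison 1 probe was higher and another lower, each by 2-fold or more. Smaller disagreements in direction were not counted, and the median range between the probes of a gene was 0.406 to 0.823.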
